A study of Mus musculus with 4 samples.

How the data were processed

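ZMYM2, a zinc finger protein known as a component of LSD1-containing repressor complexes, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse embryonic stem cells. Per the labels, the cells were of line CJ7 (strain 129S1/SVImJ), grown without feeders in serum and LIF, and carried a triple FLAG tag at the C-terminus of the endogenous Zmym2 gene. The antibody was against FLAG. There were 2 ChIP libraries and 2 input libraries, labelled as biological replicates 1 and 2 of each kind, and single-end reads of 50 bp were sequenced on an Illumina instrument. The groups were taken from the sample titles.

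The values used were those of a single deposited peak list with 26647 peaks in the 10-column narrowPeak layout. It has no header. Per the submitters' processing notes, FastQC 0.10.1, Bowtie 1.0.0 and SAMtools 0.1.19 were used and the genome build was mm9. The peak caller, its settings, the treatment of reads that map to several places, and whether the replicates were pooled before calling are not given in the sources used here. Its peak names share the prefix 3WT_Zmym2Flag, whose meaning is not given in the sources used here, and number no replicate, so no value per replicate, no SD and no test between ChIP and input libraries was possible, and each peak has 1 value. The depth of the libraries is unknown.

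For each peak the authors deposited a fold enrichment at the summit (a linear ratio of ChIP to background), the −log10 of its p-value and of its q-value, a score, and the offset of the summit from the start of the peak. The deposited score equalled the whole part of 10 times the −log10 q in all 26647 peaks. No peak in the deposited list had a −log10 q under 10. These values are the authors' own, and were used here to describe, rank and filter peaks within the list. Positions are in mm9, given from 1.

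The pileup of fragments at each summit and the background it was compared with were recovered here from the fold and the p-value. Both were solved for with the formulas that MACS2 uses, in which the fold is (pileup + 1)/(background + 1) and p is the upper Poisson tail of the pileup at that background. A whole-number pileup gave the deposited −log10 p within 0.001 in 100% of the peaks. On 5000 simulated peaks the pileup was recovered in 100%, and a wrong p gave a whole pileup in 0.02%. The lowest background was 6.16 fragments, shared within 0.001 by 33.8% of peaks. It is read here as a floor common to all chromosomes, not as a local value. Of the other peaks, 48.0% had a background on whole multiples of 0.812, within 0.002, against 0.51% of random backgrounds. A further 34.6% lay on multiples of 0.197 only, the step of a 1 kb window for fragments of 243 bp, against 1.61% of random backgrounds. The smallest peak width was also 243 bp. Each background read thus counted as 0.812 fragments at the depth of the ChIP data. The caller itself is inferred from the values, not stated in the labels.

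The only gene table at hand was RefSeq for GRCm38.p6, another build than that of the peaks. On 10 of 21 chromosomes the last peak lay beyond the last gene of that table, by up to 7.15 Mb. Peaks were therefore not assigned to genes, promoters or repeats, and sequence composition and motifs were not analysed. The gene lists and annotation tests fixed before the data were examined were not run. Apart from this comparison of chromosome ends, only the number of protein-coding genes on each chromosome was used from that table, and none of its coordinates.

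Peaks per chromosome were compared with the share of each chromosome in the summed span between its first and last peak, by a two-sided exact binomial test with Benjamini-Hochberg adjustment over the 21 chromosomes. Intervals on these ratios and on shares are exact 95% (Clopper-Pearson) intervals and cover counting error only. Peaks that lie near one another are not independent, and no p-value here measures the spread between biological replicates. Spacing was the share of peaks with the midpoint of another peak within 10 kb. It was compared with 100 random placements of the same widths within the span of the same chromosome, where placed peaks may overlap, so the smallest possible p is 0.0099. Peaks were also counted in windows of 1 Mb. The relation of score to width was a Spearman correlation across peaks with 1000 permutations of the widths. The positions named are the 10 highest-scoring peaks, by a rule fixed before the data were examined. The densest windows, longest runs of peaks, widest peaks, longest gaps and the peaks on the sex chromosomes were ranked after the data were seen.

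On peaks simulated on the real spans, a chromosome raised by 1.3 times gave a ratio of 1.28, uniform peaks gave 0 of 21 chromosomes past the threshold and a spacing ratio of 0.992, and placing 20% of the peaks beside another gave a spacing ratio of 2.19. In the chromosome test the simulated peaks were drawn independently, so the 0 of 21 does not give its error rate on clustered peaks. Alternatives were the strictest 50% and 10% of peaks by −log10 q, neighbouring peaks counted once or merged, spacing windows of 1 and 100 kb, gene numbers in place of spans, and leaving out 92 peaks with a background over 3 times the lowest. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.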

Results

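ZMYM2 occupancy in mouse embryonic stem cells was read from 1 list of peaks. The study sequenced 2 ChIP libraries of cells with FLAG-tagged endogenous ZMYM2 and 2 input libraries, and the list does not say which of them entered it. The design asks where in the genome the tagged protein was enriched over background. No FLAG ChIP of untagged cells is among the samples, so signal of the antibody that does not come from ZMYM2 could not be told apart. The list held 26647 peaks, which together covered 16.0 Mb of mm9. Median enrichment at the summit was 5.68-fold (quartiles 4.70 and 7.70), and the highest was 62.3-fold. The median −log10 q was 19.4 (quartiles 13.1 and 33.9). A total of 3257 peaks (12.2%) exceeded 10-fold enrichment, 350 exceeded 20-fold and 26 exceeded 40-fold. With 1 value per peak there is no replicate error for any single peak, and the depth of the libraries is unknown.

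At the summits, the recovered pileup had a median of 48 fragments (quartiles 39 and 65), over a median background of 7.01 fragments. At the lowest background in the list, 6.16 fragments, the smallest pileup among the listed peaks was 31. Weaker sites were therefore not detectable in this list.

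The strongest sites were spread over many chromosomes. By the score in the authors' deposited table, the first was on chromosome 12 at 44073460 to 44074565, with 62.3-fold enrichment and a pileup of 445 fragments. The second lay on chromosome 13 at 54850620 to 54852995, with 58.8-fold enrichment and 420 fragments. The third was on chromosome 9 at 21754264 to 21755608, with 39.9-fold enrichment and 460 fragments over a higher background of 10.6. Sites of 55.9-fold on chromosome 14 (64331485 to 64332453) and 46.8-fold on chromosome 18 (83712476 to 83714066) followed. The next were 39.4-fold on chromosome 2 (32872742 to 32874495) and 46.4-fold on chromosome 4 (152173341 to 152174288). A second site on chromosome 12 (25109463 to 25110455) reached 46.0-fold. The last of the 10 highest-scoring sites were 52.4-fold on chromosome 15 (76351905 to 76353441) and 34.7-fold on chromosome 8 (87470661 to 87471724). Which genes these sites lie in was not analysed here.

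Most sites were narrow. Median peak width was 491 bp (quartiles 391 and 688), the summit lay at a median of 49.3% of the peak's length, and 2658 peaks (9.97%) were wider than 1 kb. Only 58 peaks exceeded 3 kb. The widest was 9364 bp on chromosome 18 (21104226 to 21113589), with a 5.95-fold summit, followed by 8280 bp on chromosome 14 (15179517 to 15187796) at 4.17-fold and 7759 bp on chromosome 5 (109979298 to 109987056) at 12.6-fold. Stronger peaks were wider. Median width was 399 bp in the lowest 20% of peaks by score and 647 bp in the highest 20%. Across peaks, which are not independent replicates, Spearman's rho of score and width was 0.40, with a permutation p of 0.001, the smallest that 1000 permutations can give. Score and width come from the same pileup, and a taller pileup can pass the cut over a longer stretch. A positive relation was thus at least partly built into the calling.

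The density of peaks differed between chromosomes, and chromosome X had the lowest. The 19 autosomes together held 10.9 peaks per Mb. Chromosome X held 309 peaks, or 1.89 per Mb, which is 0.173 times the autosomal density. Among autosomes the density ranged from 7.75 peaks per Mb on chromosome 14 to 15.0 on chromosome 11, followed by chromosome 8 with 14.3 and chromosome 17 with 14.0. Against the share of each chromosome in the span of the peaks, 9 chromosomes held more peaks than expected, 8 held fewer and 4 did not pass the exact binomial test after Benjamini-Hochberg adjustment. By the exact binomial test, the ratio to the expected number was 1.45 on chromosome 11 (95% interval 1.38 to 1.51, adjusted p = 2.81e-50), 1.38 on chromosome 8 (1.32 to 1.44, adjusted p = 4.89e-41) and 1.36 on chromosome 17 (1.29 to 1.43, adjusted p = 6.64e-26). It was 0.183 on chromosome X (0.163 to 0.204), 0.749 on chromosome 14 (0.702 to 0.798) and 0.768 on chromosome 12 (0.720 to 0.818). These intervals count peaks as independent, and neighbouring peaks are not, so the intervals are too narrow and the p-values too small.

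**Figure D1:**
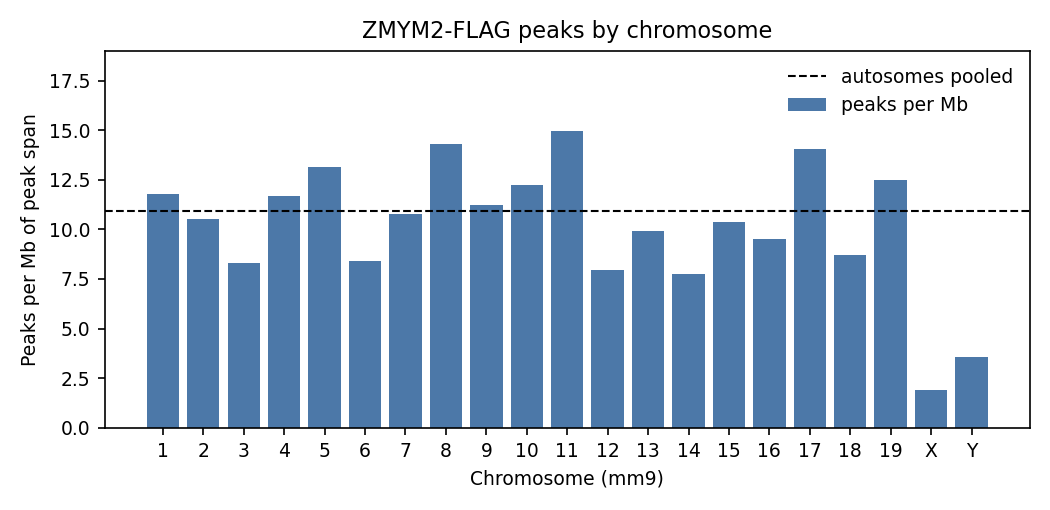
Bars give the number of peaks per Mb of the span between the first and last peak of each mm9 chromosome, and the dashed line the 19 autosomes pooled (10.9 peaks per Mb). Chromosome 11 reaches 15.0 peaks per Mb and chromosome X 1.89; the bar of chromosome Y rests on 8 peaks.

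Part of the order of chromosomes depended on what the peaks were set against. With the number of protein-coding genes per chromosome (RefSeq, GRCm38.p6) as the expected share, chosen after the data were seen, 10 of 21 ratios crossed 1, and 11 chromosomes held more peaks than expected, 9 held fewer and 1 did not pass the same test. The 9 include chromosome Y (ratio 0.0257), with 8 peaks in a span of 2.25 Mb against 256 genes counted on the other build. The 2 builds may not cover the same part of Y. The ratio for chromosome 11 turned to 0.908, that for chromosome 12 turned to 1.13 and that for chromosome 17 fell to 1.01. Chromosomes 1 and 8 stayed above 1, with ratios of 1.56 and 1.45 against 1.14 and 1.38 by span. Chromosome X stayed below, at 0.263. Chromosome 1 held 1.90 peaks per protein-coding gene and chromosome 8 held 1.76, whereas the other 17 autosomes held 0.793 to 1.55 and chromosome X held 0.320.

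The background under the peaks also set chromosomes 1, 8 and X apart from the remaining 17 autosomes. Its median was 9.48 fragments on chromosome 1 (quartiles 7.31 and 11.4) and 9.75 on chromosome 8 (quartiles 7.90 and 11.4), against medians of 6.32 to 7.26 on the other 17 autosomes. Median pileup was 56 fragments on chromosome 1 and 55 on chromosome 8, against 45 to 48 on the others. Median fold enrichment was lower there, 5.39 on chromosome 1 and 5.12 on chromosome 8, against 5.59 to 5.87. On chromosome X, 94.2% of the peaks had the lowest background in the list, against 27.1% to 48.3% on those 17 autosomes, and the median pileup was 40 fragments. A local background on X below that floor would not be seen. Chromosome Y, with 8 peaks, had the same median background as X, with 75% of its peaks at the lowest value.

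**Figure D2:**
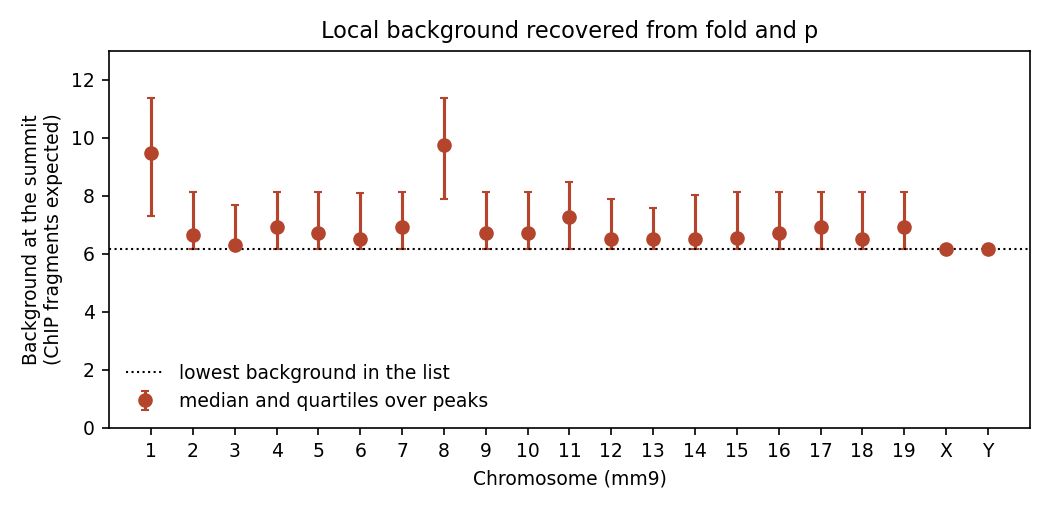
Points give the median background at peak summits on each mm9 chromosome, in expected ChIP fragments, and bars the quartiles over peaks; the dotted line is the lowest background in the list (6.16). Chromosomes 1 (9.48) and 8 (9.75) lie above the other autosomes (6.32 to 7.26), and chromosome X lies at the lowest background.

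Chromosome X also held a smaller share of strong peaks, although the floor of 6.16 fragments may lower its folds. Of its 309 peaks, 19 exceeded 10-fold enrichment (6.15%, exact 95% interval 3.74 to 9.44), against 3236 of 26330 autosomal peaks (12.3%, 11.9 to 12.7; odds ratio 0.468, two-sided Fisher's exact test, p = 0.000602). Its strongest site, at 71114489 to 71115391, was nevertheless 46.5-fold enriched, with a pileup of 332 fragments. The next on X were 27.0-fold at 146801155 to 146802249 and 22.5-fold at 73751035 to 73751623. Chromosome Y held 8 peaks between 403678 and 2653755, of which those at 2619061 to 2619582 (27.4-fold) and 1140070 to 1140572 (17.5-fold) exceeded 10-fold.

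Peaks lay closer together than random placement gave. Another peak lay within 10 kb of 11117 peaks (41.7%), against a mean of 19.9% and a highest value of 21.0% in 100 random placements on the same chromosomes. The ratio was 2.09 (permutation p = 0.0099, the smallest that these placements allow). It lay between 1.80 on chromosome 11 and 4.61 on chromosome X over the 20 chromosomes with at least 100 peaks, each with the same p. These ratios do not rank chromosomes by clustering, since the random share rises with peak density. On chromosome 11 the share was 46.5% against a random mean of 25.8%, and on chromosome X 17.2% against 3.72%. In the strictest 10% of the peaks by −log10 q, which are sparser, the ratio was 3.83, from a share of 8.86% against a random mean of 2.31%. Peaks with a neighbour had a slightly lower median fold, 5.55 over 11117 peaks, than the 15530 lone peaks, with a median of 5.73. The difference of 0.18 had a two-sided permutation p of 0.001, the smallest that 2000 resamples can give, with peaks counted as independent. A higher background lowers the fold, and pileup, background and chromosome were not compared between these sets, so a weaker signal is not shown.

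**Figure D3:**
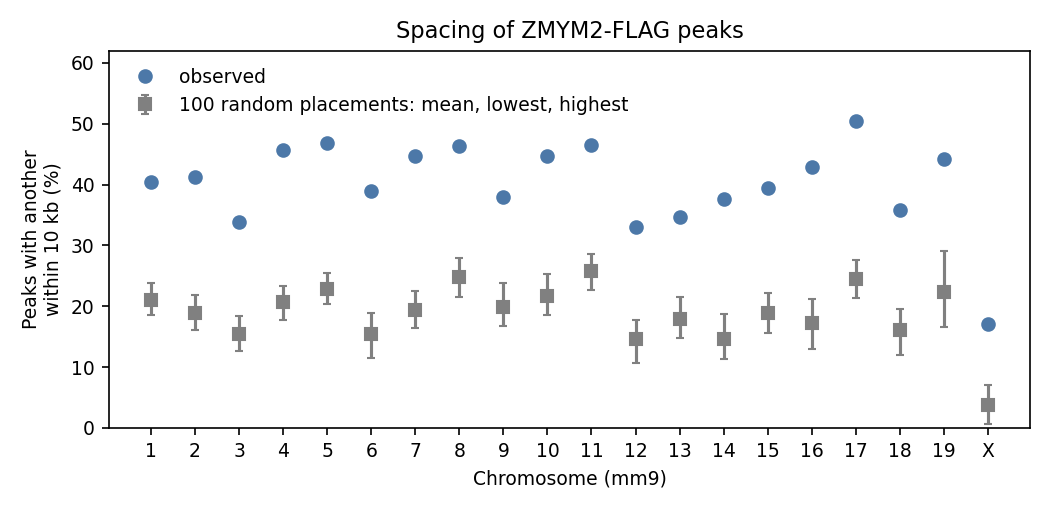
Circles give the percentage of peaks on each mm9 chromosome with another peak within 10 kb, and squares with bars the mean, lowest and highest of 100 random placements. The observed share is above the random placements on all 20 chromosomes shown. Its ratio to the random mean, which depends on peak density, is 1.80 on chromosome 11 and 4.61 on chromosome X.

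Some neighbouring peaks formed long runs. Linking peaks within 10 kb gave 296 runs of 5 or more peaks and 49 of 8 or more. The longest, with 15 peaks, covered 60.9 kb of chromosome 10 (82862936 to 82923844), with a strongest peak of 10.2-fold. Runs of 14 peaks lay on chromosome 13 (21987848 to 22037208, strongest peak 21.4-fold), chromosome 4 (130163612 to 130202599, 13.7-fold) and chromosome 7 (3183902 to 3230282). A second run on chromosome 13, of 12 peaks, lay at 21291935 to 21342304.

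On a larger scale, autosomal peaks were unevenly spread. In 2419 windows of 1 Mb the autosomes held a median of 8 peaks (mean 10.9 ± 9.92, SD over windows). The densest 10%, 242 windows, held 30.8% of autosomal peaks, against 16.8% on average and 17.1% at most in 100 random placements. The densest window, chromosome 17 from 29000001 to 30000000, held 73 peaks, and the window from 27000001 on the same chromosome held 56. Chromosome 7 from 29000001 to 30000000 and chromosome 10 from 80000001 to 81000000 each held 62. No peak lay in 72 autosomal windows (2.98%, exact 95% interval 2.34 to 3.73) and in 47 of 164 windows of chromosome X (28.7%, 21.9 to 36.2). A Poisson count at the same means gives 0.0453 empty windows on the autosomes and 24.9 on chromosome X. Much of the number on X thus goes with its low peak count. The variance over windows was 9.04 times the mean on the autosomes and 2.32 times on X. The longest stretches without a peak were 7.63 Mb on chromosome 7 (39086107 to 46711132) and 6.79 Mb on chromosome X (23729327 to 30517680). Gaps in the assembly and places where 50 bp reads do not map were not separated from such stretches.

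**Figure D4:**
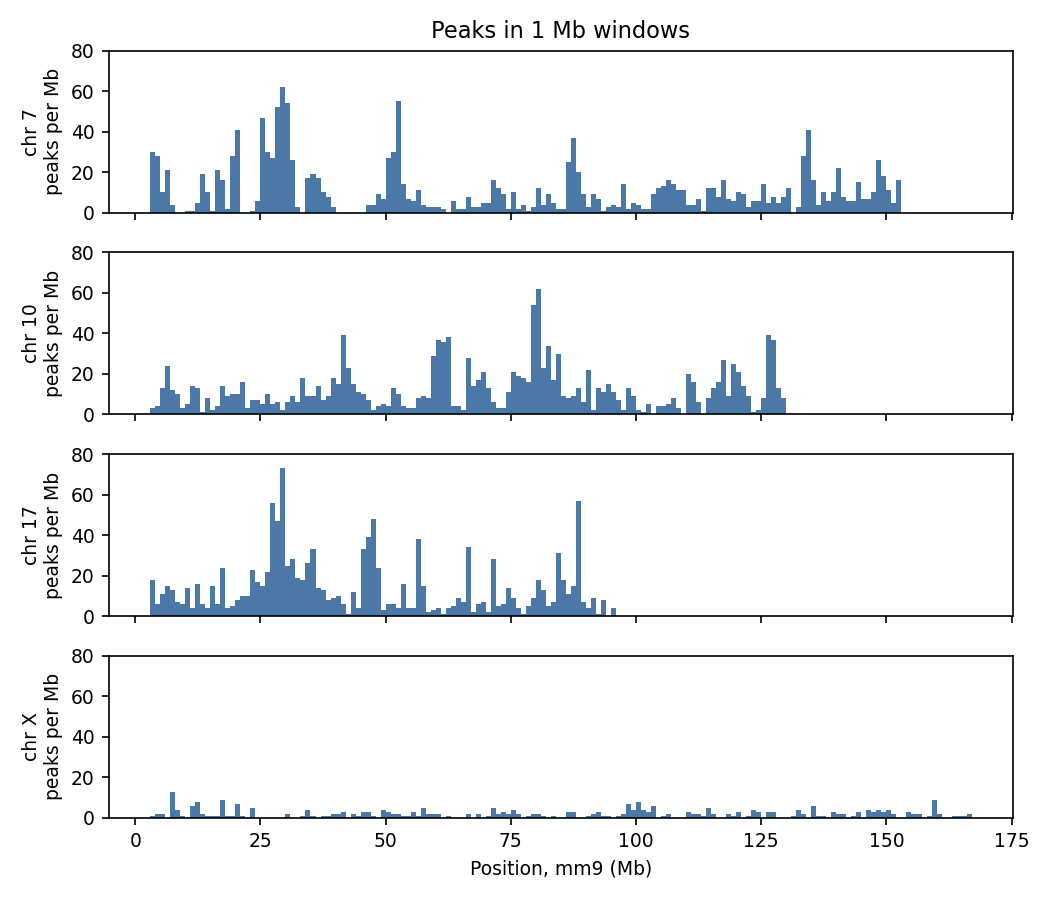
Bars give the number of peaks in each 1 Mb window along mm9 chromosomes 7, 10, 17 and X, on a shared scale. The window of chromosome 17 that starts at 29 Mb holds 73 peaks, and 47 of 164 windows of chromosome X hold none, where a Poisson count at its mean gives 24.9.

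A small group of peaks stood on high background. In 92 peaks on 18 chromosomes the background was over 3 times the lowest, and their median enrichment was 3.28-fold. The highest backgrounds, 252 and 229 fragments, were under adjacent peaks of 1.68-fold and 1.76-fold on chromosome 17 (39979930 to 39983752 and 39984266 to 39985816). Chromosome 11 had the next, 171 fragments at 3092467 to 3094187. The median background of the 92 peaks was 21.1. Chromosomes 1 and 8, where the median background was higher, held 24 and 27 of the 92 peaks. Of the 26 peaks with a background over 5 times the lowest, a limit set after the data were seen, chromosome 1 held 0 and chromosome 8 held 6.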

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

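Leaving out peaks of high background and setting peaks against gene numbers were chosen after the data were seen, as were all alternatives for score against width. Of 127 alternative values, 104 kept their direction and, where there was a threshold, their side of it. Descriptions of the list and of score against width had no threshold. Of the 105 chromosome ratios among the 127, 13 reversed. With peaks counted as independent in every run, chromosomes 1, 4, 5 and 8 (more peaks) and 14 and X (fewer) kept direction and side in each alternative. So did the spacing at 10 kb (ratios 2.09 to 3.83) and at 1 kb (1.11, permutation p = 0.0396). At 1 kb, however, the observed 2.47% lay within the range of the random placements, 1.85% to 2.66%. Placed peaks may overlap, whereas only 4 pairs of called summits lay under 0.5 kb apart, so the 1 kb comparison is not like with like. At 100 kb (1.01) the measure is saturated, with 88.0% of peaks near another in random placements, and cannot show clustering. The number of chromosomes past the threshold fell from 17 to 10 in the strictest 10% of peaks, where fewer peaks were tested. In autosomal windows of 1 Mb the variance of the peak count was 9.04 times its mean, far above that of independent peaks. The binomial p-values are therefore too small in every alternative. Small departures such as 1.14 on chromosome 1 and 1.13 on chromosome 4 remain uncertain. Small departures from 1 reversed among chromosomes that had not passed: chromosome 2 to 0.980 in the strictest 10%, chromosome 13 to 1.02 with peaks within 10 kb counted once, and chromosome 15 to 0.954 in the strictest 50%. Gene numbers as the expected share reversed chromosomes 2 (0.867), 7 (0.651), 9 (0.925), 11 (0.908) and 19 (0.847) to below 1, and chromosomes 3 (1.09), 12 (1.13), 13 (1.14), 16 (1.09) and 18 (1.23) to above 1. These follow from the number of genes per Mb. A further 8 chromosome ratios no longer passed and 1 newly passed in some alternative. The list holds no chromosomes other than 1 to 19, X and Y, so keeping only these removed nothing. No paired analysis was possible because the list gives no value per replicate, and for the same reason no replicate could be left out. The planned full-length and unmasked denominators, promoter windows, gene lists, composition, motifs and repeat families were not run, since no genome or annotation of mm9 was at hand. The depth is unknown; a pileup under 31 fragments passed at no peak on the lowest background, where 94.2% of the peaks of chromosome X lie.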

Other observations

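The tests of background and of gene numbers on chromosomes 1, 8 and X, and that of paired LTRs, were chosen after the result was seen; the tests that scale or halve the peaks were written down before.

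Chromosomes 1 and 8 had a higher background and more peaks per protein-coding gene than the other 17 autosomes. Per Mb, their 11.8 and 14.3 peaks lay inside the range of those autosomes, 7.75 to 15.0. The median background was 1.41 times the median of those autosomes on chromosome 1 and 1.45 times on chromosome 8. Without the peaks of high background the lower of these ratios was still 1.39, but these were only 24 and 27 peaks on chromosomes 1 and 8. Leaving out so few peaks could hardly move a median, so this cannot test whether a few repeated regions were the cause. Bins of 20 Mb argue against a few repeated regions: 16 of 17 on both chromosomes lay above 7.26, the highest median of another autosome. The exception was chromosome 1 from 100000001, with a median of 6.70 over 98 peaks. None of 116 bins on the other autosomes exceeded 9.48, the lower of the medians of chromosomes 1 and 8. That bar is higher than 7.26, and some bins of chromosomes 1 and 8 also missed it (8.67 on chromosome 1 from 40000001). How many of the 116 bins exceeded 7.26 is not given here. A candidate explanation for the background is an extra copy of both chromosomes in part or all of these cells. Whether extra copies also account for the peaks per gene stays open: scaled from 3 to 2 copies, 1.21 per gene passed on chromosome 1, but this scaling removes 36.1% to 52.1% of the peaks of any autosome, where a loss of 18.4% was enough to enter the range of the others. The background is seen only under peaks, the replicates cannot be separated, and whether binding itself differed on these chromosomes was not tested.

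Chromosome X had 0.320 peaks per protein-coding gene. Fewer genes alone are argued against, since the lowest autosome had 0.793. Fewer reads, as a single copy gives, may account for most of the gap: after halving the pileup, and the background down to the lowest value of 6.16 but not below it, 23.5% to 28.8% of the peaks of each autosome other than 1 and 8 still passed, and peaks per gene then lay between 0.217 and 0.413. In the list, 94.2% of the X peaks have that lowest background. Of the 5899 peaks of those autosomes that passed, 8.44% exceeded 10-fold, inside the interval of the X share (3.74% to 9.44%). Per Mb, X lay below the halved autosomes (1.89 against 2.05 to 4.07), so a lower density of sites on X stays open.

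The series title names LTRs of the endogenous retrovirus MERVL. Full-length copies carry an LTR at each end, so binding at both ends might show as pairs of summits 5.5 to 6.5 kb apart. There were 869 such pairs, 0.962 times the mean of the flanking kilobases from 4.5 to 7.5 kb (95% interval 0.887 to 1.04, two-sided exact binomial p = 0.356), and the upper limit allows 0.298% of the peaks in excess pairs. No excess of such pairs was thus seen in this list. The interval counts pairs as independent, but a peak in a run can enter several pairs. It is therefore too narrow, and its upper limit is only approximate. Single LTRs, and copies too alike for 50 bp reads to be placed, are not covered by this test.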
